A study of Saccharomyces cerevisiae with 137 samples.

How the data were processed

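Microarrays with a pair of dyes measured yeast transcripts in 137 arrays from 30 flasks of 7 strains, each array comparing a sample taken at 13 °C or during recovery at 30 °C with the t0 sample of its own flask. Strain, time, flask number, dye orientation, chip source and slide coating were taken from the labels, and all 137 columns were mapped to a sample (unmapped columns 0). The GCAT chips held 9 arrays, all of wild-type flasks 0 and 1, and the Ontario chips the other 128; 30 slides were uncoated, those of dHAP4 and of dSWI4 flasks 2 to 4. Arrays per strain numbered 23 for wild type, 20 each for dCIN5, dGLN3, dHMO1 and dZAP1, 18 for dHAP4 and 16 for dSWI4. Per the labels 2 flasks of a strain were grown on the same day, and each flask was treated here as 1 replicate. Which flasks shared a day is not given in the sources used here, so the day is not in the model, and flasks of one day may be less independent than the printed n implies.

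The deposited values are a score, 1 per open reading frame and array: a log ratio of the shifted sample over t0 that the authors made with limma, whose version is not given in the sources used here. Background correction, normalization within arrays and spot filters are likewise not given. On every array the scaled median absolute deviation was 0.997 to 1.003 and the median −0.051 to 0.085, so that 1 unit is 1 scaled median absolute deviation of that array. The plan, written before the data were examined, took the values for log2 ratios; the values show otherwise, and no folds are given. Of 6178 open reading frames, 5674 matched a locus tag of the gene table and 504 did not and keep their systematic names. Among the latter, YMR173W-A, YKL111C, YFL012W-A and YCLX11W are named below. They had no position in the gene table, so that their overlap with other genes was not examined. Of all values 3.95% were missing, and 1316 frames had a value on every array. Signal and background intensities were not analysed here, and the number of arrays limits the precision.

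Genes were tested in limma (limma 3.58.1, R 4.3.3) with 1 mean per time, flask as a random block with a correlation estimated over genes (0.11 to 0.4 by strain), moderated variances and Benjamini-Hochberg adjustment, at an adjusted p below 0.05 and with at least 2 flasks per group. Wild type was tested at each time and between recovery and t60, each deletion strain at t60 and t120, and each deletion strain against wild type on the mean of t30 and t60 and on the mean of t90 and t120. Of 34 gene lists fixed at the start, 33 were tested with cameraPR at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list; the transcripts encoded in mitochondria are not on the array. The pattern that picks cytosolic ribosomal proteins also takes RPP1, a subunit of RNase P. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

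Genes named in the text follow a rule fixed at the start: in wild type the 8 highest and 8 lowest at t60, and 4 and 4 at other times and for t120 against t60, among genes past the threshold with the same sign in every flask; 4 and 4 per deletion comparison among genes whose flask means do not overlap between the strains; 2 and 2 per deletion strain at t60; up to 4 members of each list with the smallest adjusted p; and the 6 deleted factors. A result that this rule also picks is not reported here. Each gene picked by size in a strain tested against t0 therefore had the same sign in all its flasks. List members and the deleted factors were picked without regard to the sign in single flasks.

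The fit was tested on simulated data. With 200 changed genes at the wild-type t60 design, 12 of 100 changes of size 1 and 71 of 100 of size 2 were found, and 3 of 86 calls were false. Over 21 comparisons, simulated once each, 102 of 1823 calls were false (5.6%), more than 5% in 12 of them and up to 8 of 86 (9.3%) for dHMO1 minus wild type in recovery. For dCIN5 minus wild type in cold, 57 of 100 changes of size 2 were found. Of 640 unchanged lists 25 had p below 0.05 in cameraPR with the preset correlation. The simulated genes were drawn independently of each other. This count therefore does not show how the preset correlation holds for real lists, whose members can be correlated. The alternatives tried were no replicate block, a dye orientation term, arrays centred, arrays centred and scaled, genes measured on every array, robust moderation, the Ontario chips only, each flask left out, an adjusted p below 0.01, 1 fit of all strains, flask number as a block, a slide coating term for dSWI4, t60 or t120 alone, and the estimated correlation. Leaving out the 4 arrays that resembled the other phase and turning the signs of dHMO1 flask 2 or 4 were chosen after seeing the data. No genome sequence or probe annotation was used here, so that cross-hybridization between similar genes was not examined.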

Results

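Transcript levels of budding yeast (Saccharomyces cerevisiae) were followed through a shift from 30 °C to 13 °C and back. Cultures grown in rich medium were sampled before the shift (t0), after 15, 30 and 60 min at 13 °C (t15, t30 and t60) and after 30 and 60 min of recovery at 30 °C (t90 and t120). Each of 137 arrays compared a shifted sample, in one dye, with the t0 sample of the same flask, in the other. The 30 flasks, separate cultures per the labels, belonged to wild type (5 flasks) and to strains that lack 1 of 6 transcription factors: Cin5, Gln3, Hap4, Hmo1, Swi4 or Zap1 (25 flasks, named dCIN5 to dZAP1 here). Wild type had 4 arrays at t15 and t60 and 5 at the other times. The deletion strains had 4 at each time, except that dHAP4 had 3 at t90 and at t120 and that no t15 array of dSWI4 was analysed here. An array measured 5041 to 6158 of the 6178 open reading frames (median 5974). Values are the authors' scaled log ratios of shifted sample over t0, in units of the array's own spread, so that they are not folds and their sizes do not compare as folds between arrays. The p-values of single genes rest on a moderated variance per gene that pools all times and strains of the fit. They also use a flask correlation common to all genes of a fit. They do not rest on the SD over flasks at a given time, which is printed beside many means. Those of gene lists rest on how the mean statistic of the list's genes differs from that of the other genes, given a correlation between genes. A few extreme members can therefore weigh on them. The small number of arrays per group limits the precision.

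The cold and the recovery profiles differed over genes (Spearman rho = −0.31 between the median profiles of the 2 phases, across genes, which are not independent). The arrays taken to look like the other phase, by a rule chosen after seeing the data (rank correlation below 0 with their own phase and above 0.1 with the other), were the 4 arrays dGLN3 t60 flask 2, dHAP4 t90 flask 4, dHMO1 t60 flask 3 and dHMO1 t90 flask 3. Their rank correlation with their own phase in the other strains was −0.32, −0.17, −0.06 and −0.23, against 0.29, 0.62, 0.12 and 0.49 with the other phase. Shifted over t0 is the likely direction of the ratio, from the titles alone. Arrays of one group with opposite dyes correlated positively (median r = 0.332 over 137 pairs, 120 of them above 0). Both dye orientations were thus likely turned alike, which does not show in which direction. For dHMO1 the direction is not settled, since the t15 arrays of flasks 3 and 4, both of one dye orientation, correlated at r = −0.476. Results of dHMO1 are therefore also given with the sign of flask 2 or of flask 4 turned.

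**Figure D1:**
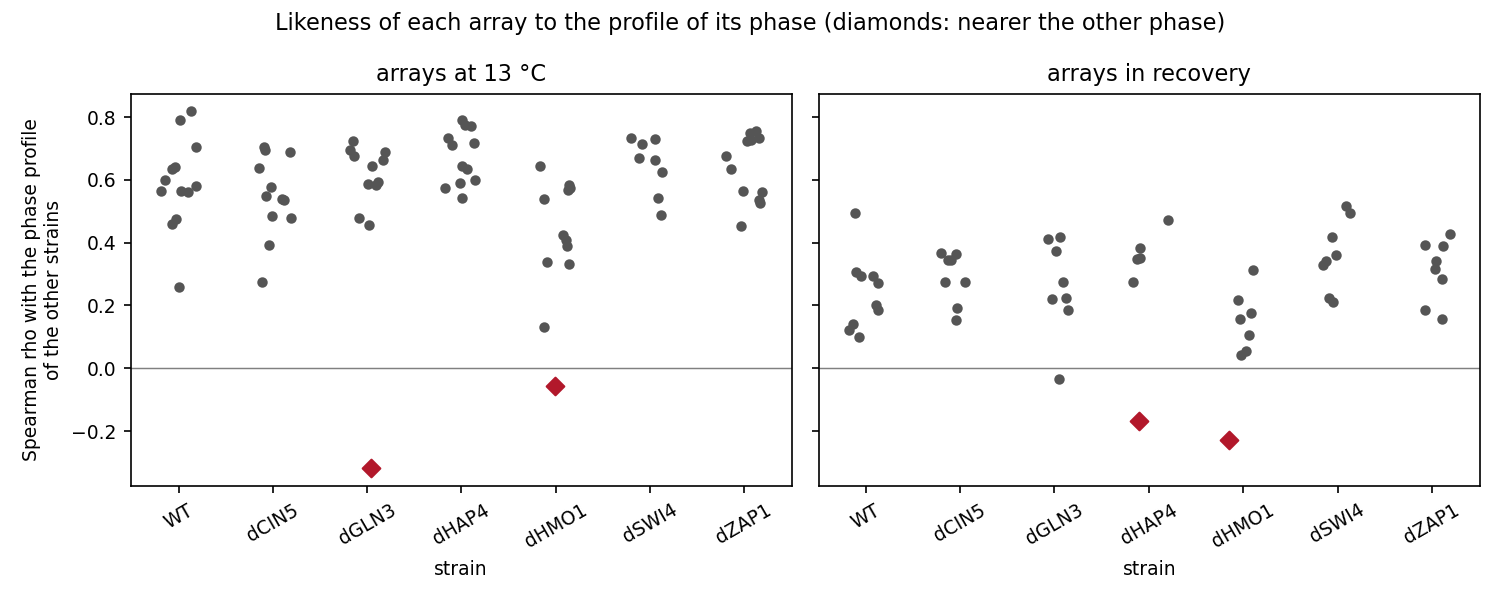
Rank correlation of each array with the median profile of its own phase in the other strains, across genes, 1 point per array. Arrays taken in cold and in recovery are shown separately. The 4 arrays that met the rule had values of −0.32 to −0.06 with their own phase, and the array of dGLN3 at t60 lay lowest.

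Which transcripts change during cold shock was asked by testing the wild-type ratio against 0 at each time. At t60 the gene with the highest mean was NCE103, which encodes carbonic anhydrase, at 6.46 ± 1.91 (SD, n = 4 flasks, adjusted p = 0.00065). EFM6, a methyltransferase of a translation elongation factor, rose to 6.26 ± 1.16 (adjusted p = 2e-07). The membrane proteins IZH4, IZH1 and IZH2, linked to zinc homeostasis, rose to 5.14 ± 1.27, 4.74 ± 1.01 and 4.65 ± 1.04 (adjusted p = 0.00037, 0.00033 and 1.4e-06), and the uncharacterised YDR042C to 4.83 ± 1.02. ARO5 and ARG4, the latter the last enzyme of arginine synthesis, rose to 4.57 ± 1.75 and 4.51 ± 2.28. ZEO1, whose product is a peripheral membrane protein, fell most, to −4.49 ± 1.32 (adjusted p = 0.00011). HSP42, a small heat shock protein, had a mean of −3.56 ± 0.61 and a fitted value of −3.01 (adjusted p = 0.028). IDH1 and IDH2, the subunits of mitochondrial isocitrate dehydrogenase, fell to −3.26 ± 1.1 and −3.34 ± 1.52, with flask 0 apart from the others in IDH2 at −1.06. HSP78 (−3.09 ± 1.52), CAR2 (−3.1 ± 1.23), STE18 (−2.96 ± 0.58) and CAP2 (−2.88 ± 0.42) also fell. All 16 genes moved the same way in 4 of 4 flasks, as the rule that picked them requires. In all, 971 of 6172 genes changed (570 higher, 401 lower; limma, adjusted p below 0.05). The count was 541, 643 and 623 without flask 2, 0 or 1, and 464 with the Ontario chips alone, which leaves out flasks 0 and 1. On those chips the calls of HSP78, STE18 and HSP42 were lost, and HSP42 was also lost without any 1 of flasks 0 to 3.

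**Figure D2:**
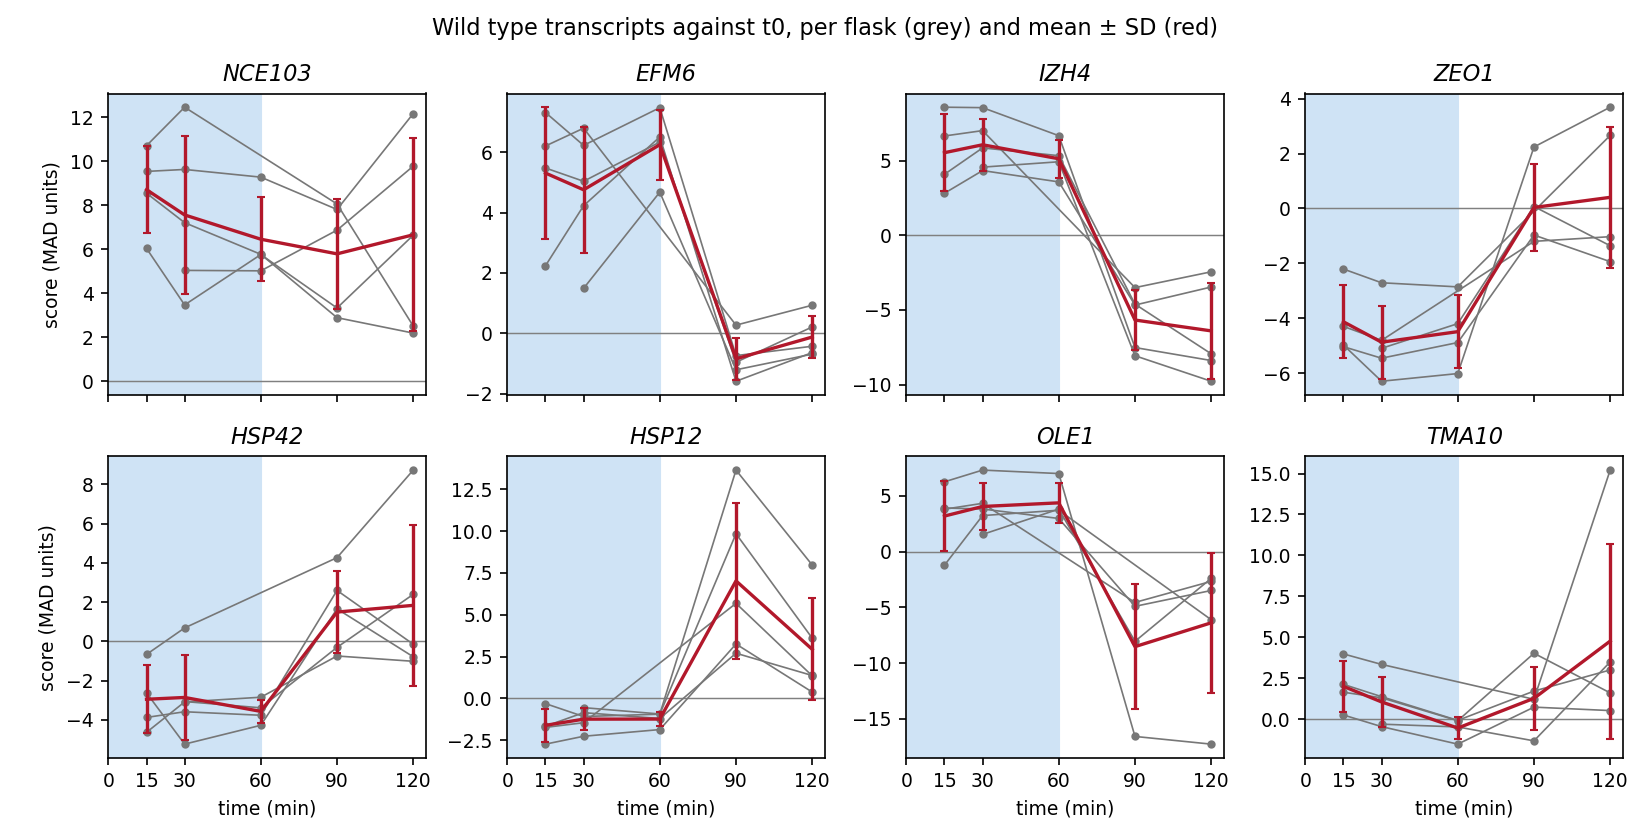
Wild-type score (y axis, units of the array's spread) against time (x axis, min) for 8 genes; grey lines are flasks, red points are means with SD, and the shading marks 13 °C. NCE103 had means of 8.71 at t15 and 6.66 at t120, while IZH4 went from 5.14 at t60 to −5.67 at t90.

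Genes of ribosome biogenesis, the assembly of new ribosomes, were higher at t60 as a group: 62 of 112 measured members rose, none fell in this test and 50 did not pass (88 rose adjusted over the list alone, median 1.46, adjusted p = 2.21e-27, and 0.00288 with an estimated correlation). Examples were the RNA helicase DBP2 (4.13 ± 0.58, n = 4), the nucleolar protein NSR1 (3.53 ± 0.43), CIC1 (3.11 ± 0.71) and NOP9 (2.22 ± 0.61). Heat shock proteins and chaperones went the other way, with 14 of 27 lower and 13 not past the threshold (17 lower adjusted over the list alone, median −1.52, adjusted p = 1.48e-08, and 0.029 with an estimated correlation). Among them were HSP26 (−2.18 ± 0.46), CPR6 (−2.11 ± 0.64) and HSP60 (−1.85 ± 0.59). Of 11 genes of the tricarboxylic acid cycle, 4 fell (5 adjusted over the list alone, median −0.98, adjusted p = 0.000106, and 0.029 with an estimated correlation). Besides IDH1 and IDH2 these were ACO1 (−2.14 ± 0.97) and MDH1 (−1.33 ± 0.91). Genes of DNA replication had 7 of 26 members lower (13 adjusted over the list alone, median −0.98, adjusted p = 2.55e-07, and 0.029 with an estimated correlation). They include the thymidylate synthase gene CDC21 (−2.77 ± 0.28), POL12 (−1.91 ± 0.62), CDC45 (−1.92 ± 0.4) and the S-phase cyclin CLB6 (−1.93 ± 0.23). With only genes measured on every array the call of the tricarboxylic acid cycle was lost (adjusted p = 0.063).

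Another 11 lists were called at t60 with the preset correlation and lost with an estimated one. The PAU genes, a family of near-identical cell wall genes whose probes may not tell members apart, had 15 of 23 higher (15 adjusted over the list alone, PAU1 2.5 ± 0.88, PAU6 2.03 ± 0.34; adjusted p = 3.75e-08, and 0.298 with an estimated correlation). Targets of Zap1, the activator of genes for zinc uptake, had 9 of 17 higher and 1 lower (9 and 2 adjusted over the list alone, the zinc transporter gene ZRT1 4.36 ± 0.31, ZPS1 2.67 ± 0.49; adjusted p = 0.000917, and 0.0684 with an estimated correlation). Amino acid synthesis genes had 13 of 48 higher and 4 lower (16 and 5 adjusted over the list alone, adjusted p = 0.00991, and 0.298 with an estimated correlation). Among those higher were CPA1 (4.41 ± 0.94) and ARG1 (3.67 ± 1.67), of arginine synthesis. Mitochondrial ribosomal proteins had 12 of 65 higher and 1 lower (14 and 1 adjusted over the list alone, MRPL40 2.08 ± 0.4; adjusted p = 0.00241, and 0.298 with an estimated correlation). Cytosolic ones had 11 of 136 lower (5 adjusted over the list alone, RPS28B −2.76 ± 0.53; adjusted p = 4.86e-11, and 0.354 with an estimated correlation). Cold-induced mannoproteins had 4 of 9 higher (5 higher and 1 lower adjusted over the list alone, TIR1 2.96 ± 1.56, TIP1 2.89 ± 1.2; adjusted p = 0.0464, and 0.298 with an estimated correlation). Subunits of RNA polymerase I and III had 4 of 23 higher (4 adjusted over the list alone, RPA12 1.9 ± 0.33; adjusted p = 0.034, and 0.298 with an estimated correlation). The proteasome had 4 of 32 higher (4 adjusted over the list alone, RPT3 1.49 ± 0.85; adjusted p = 0.034, and 0.385 with an estimated correlation). Glycolysis had 4 of 16 lower (5 adjusted over the list alone, ADH1 −1.55 ± 0.89, PFK1 −1.43 ± 0.53; adjusted p = 6.51e-05, and 0.298 with an estimated correlation). Trehalose and glycogen metabolism had 3 of 19 lower (3 adjusted over the list alone, GLG2 −2.07 ± 0.95; adjusted p = 0.02, and 0.385 with an estimated correlation). General stress genes had 3 of 35 lower and TPH3 higher (3 lower adjusted over the list alone, PRX1 −1.58 ± 0.3; adjusted p = 0.0335, and 0.447 with an estimated correlation).

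The 18 remaining lists were not called at t60. Their adjusted p was 0.0872 for G1 cell cycle genes (1 member higher, 4 lower), 0.107 for respiratory chain genes (1 lower), 0.235 for iron-responsive genes (2 and 2). It was 0.361 for phosphate-responsive genes (2 and 1) and for protein folding in the endoplasmic reticulum (1 and 1) and 0.368 for osmotic response genes (2 higher). It was 0.505 for purine synthesis (1 and 4) and pheromone response (0 and 0), 0.522 for translation factors (1 lower), 0.588 for histones (1 higher) and 0.719 for gluconeogenesis (2 and 1). It was 0.824 for genes specific to mating type a (1 lower), 0.836 for sulfur assimilation (2 higher), and 0.837 for fatty acid synthesis (2 and 1), ergosterol synthesis (2 and 1), Gln3 targets (2 and 2), G2/M genes (1 and 1) and genes specific to mating type alpha (0 and 0). Wild-type flask 0 was BY4739, of mating type alpha, and the other flasks BY4741, of mating type a.

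**Figure D3:**
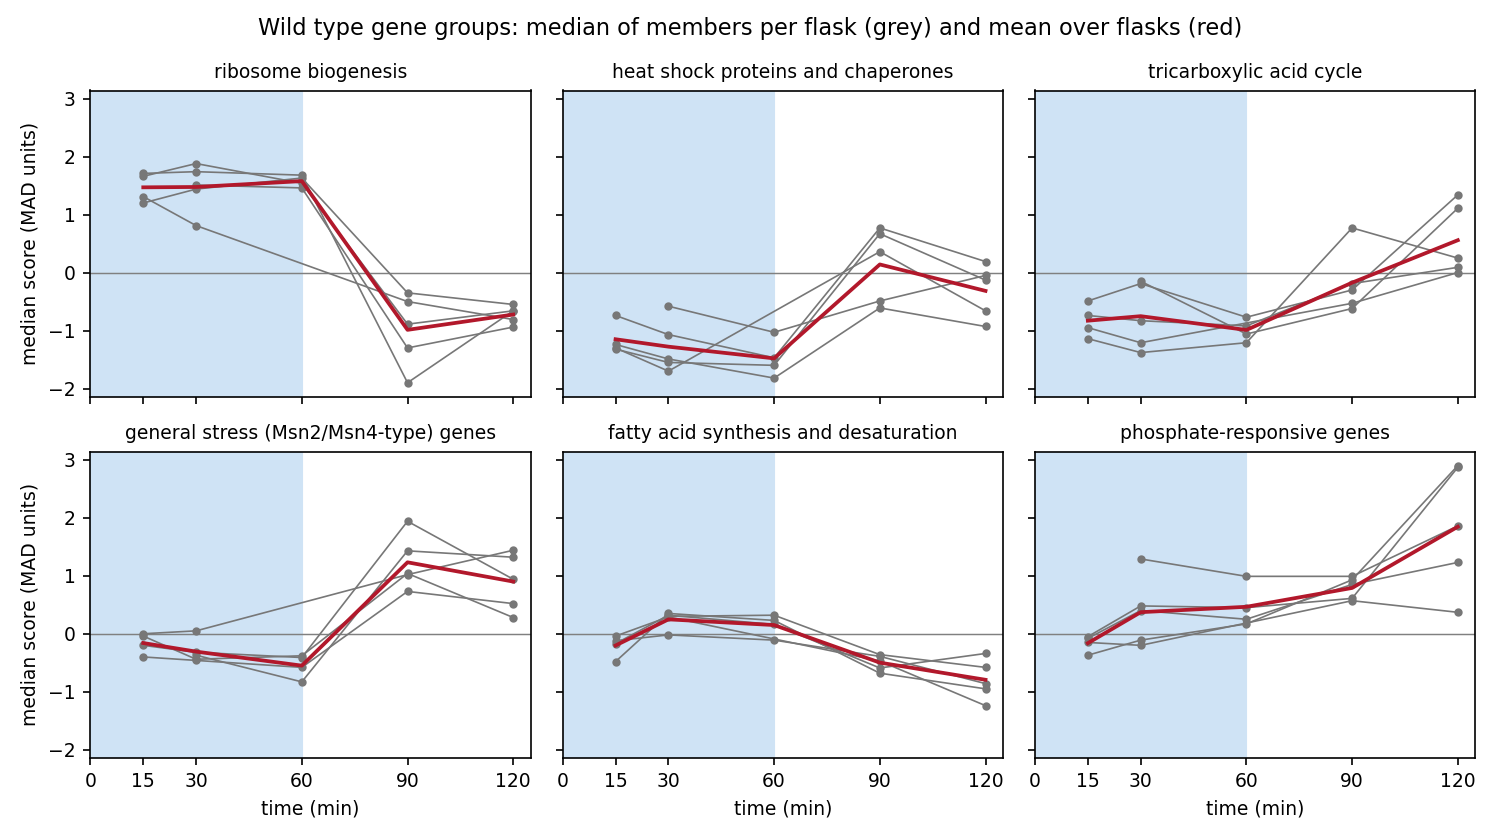
Median score of gene lists in wild type (y axis, units of the array's spread) against time (x axis, min); grey lines are flasks, red lines are the means of the flask medians, and the shading marks 13 °C. Ribosome biogenesis was higher at each cold time and lower at t90 and t120, with means of the flask medians of 1.58 at t60 and −0.99 at t90.

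The earlier cold samples were tested in the same way. At t15 NCE103 was at 8.71 ± 1.99 (n = 4, adjusted p = 7.2e-05), the uncharacterised YGR035C at 7.56 ± 2.61 with flask 1 apart at 3.65. The glucose transporter gene HXT2, of a family with similar sequences, was at 6.52 ± 4.63 with flask 2 apart at 13.42. MIG2, a repressor active in high glucose, rose to 5.35 ± 2.56 (adjusted p = 2.5e-05). BTN2 and CUR1, which sort misfolded proteins, fell to −4.75 ± 2.65 (n = 3) and −3.56 ± 2.04, ZEO1 to −4.13 ± 1.32 and the iron-sulfur scaffold ISU2 to −3.4 ± 0.81 (adjusted p = 5.2e-06). The call of BTN2 was lost without flask 3 (−3.44) and with robust moderation (adjusted p = 0.094). At t30 NCE103 (7.56 ± 3.59, n = 5), IZH4 (6.08 ± 1.76), YGR035C (5.33 ± 1.87, n = 4) and IZH1 (5.27 ± 1.88) were highest. Lowest were ZEO1 (−4.87 ± 1.33), STE18, the gamma subunit of the pheromone receptor's G protein (−3.71 ± 0.93), CUR1 (−3.1 ± 1.02) and MIT1 (−3.03 ± 1.16). Ribosome biogenesis had 59 of 112 members higher at t15 and 64 at t30 (79 and 89 adjusted over the list alone, adjusted p = 0.00182 and 0.00185 with an estimated correlation). Heat shock proteins had 10 and 14 of 27 lower (14 and 15 adjusted over the list alone, adjusted p = 0.0359 and 0.0246 with an estimated correlation). These were the 2 lists of 33 that held with an estimated correlation at either time, out of 9 and 10 called with the preset one. In all, 668 of 6172 genes changed at t15 (472 higher, 196 lower) and 933 of 6176 at t30 (582 higher, 351 lower). At t15 the count was 310, 274 and 422 without flask 2, 3 or 4, and at t30 482 and 610 without flask 2 or 3. At t15 the median and mean differed in sign for fatty acid synthesis (−0.26 and 0.15), ergosterol synthesis (0.12 and −0.09), phosphate-responsive genes (−0.04 and 0.12), translation factors (0.06 and −0.04) and endoplasmic reticulum folding (0.03 and −0.04), none of which was called.

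After 30 min of recovery (t90), HSP12, a small heat shock protein that binds membranes, rose to 7.02 ± 4.65 (n = 5, adjusted p = 3e-05), YMR173W-A to 6.36 ± 1.93, NCE103 to 5.79 ± 2.49 and HOR7 to 5.39 ± 3.26 (n = 4). Whether YMR173W-A overlaps another gene was not examined. OLE1, the fatty acid desaturase, fell to −8.51 ± 5.59 (n = 4, adjusted p = 0.005), a call lost on the Ontario chips alone (−8.67). FAA4, which activates fatty acids, fell to −6.93 ± 2.52 (n = 5, adjusted p = 1.6e-06), IZH4 to −5.67 ± 2 and DBP2 to −5.39 ± 1.71 (n = 4). General stress genes had 15 of 35 members higher (17 adjusted over the list alone, median 1.02, adjusted p = 0.00389 with an estimated correlation), such as DDR48 (5.39 ± 1.79), PNC1 (4.48 ± 2.6) and GTT1 (2.7 ± 1.3). Ribosome biogenesis had 31 of 112 lower (54 adjusted over the list alone, median −1.01, adjusted p = 0.00196 with an estimated correlation), such as NOP13 (−2.11 ± 0.86). RNA polymerase I and III had 2 of 23 lower (2 adjusted over the list alone, RPC19 −1.73 ± 0.93; adjusted p = 0.00976 with an estimated correlation). Fatty acid synthesis had 3 of 16 lower (6 adjusted over the list alone, FAS1 −1.93 ± 0.74, n = 3, adjusted p = 0.00113 with an estimated correlation). DNA replication genes had 9 of 26 higher (12 adjusted over the list alone, CDC21 2.13 ± 0.95, POL30 1.87 ± 0.43; adjusted p = 0.0106 with an estimated correlation). G1 cell cycle genes had 8 of 26 higher (9 adjusted over the list alone, TOS6 2.56 ± 1.17, CRH1 2.05 ± 0.98; adjusted p = 0.0103 with an estimated correlation). In all, 346 of 6177 genes changed (211 higher, 135 lower), a count of 183, 139 and 198 without flask 0, 2 or 3 and of 195 with the Ontario chips alone. The call of fatty acid synthesis was lost on those chips (adjusted p = 0.063).

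After 60 min of recovery (t120), 166 of 6177 genes differed from t0 (107 higher, 59 lower). Of phosphate-responsive genes 7 of 15 rose (13 adjusted over the list alone, median 1.84, adjusted p = 1.69e-15, and 1.11e-06 with an estimated correlation). Among these were the acid phosphatases PHO11 (4.23 ± 1.32, n = 5) and PHO12 (3.67 ± 0.8), which are nearly identical and may not be told apart, SPL2 (4.12 ± 2.18) and PHO5 (2 ± 0.86). Targets of Gln3, the activator of genes for poor nitrogen sources, had 4 of 28 higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 2.77e-05 with an estimated correlation). Those higher included the arginase gene CAR1 (3.5 ± 1.13), the glutamine synthetase gene GLN1 (3.22 ± 1.46) and GAP1 (2.43 ± 1.39). Fatty acid synthesis had 5 of 16 lower (8 adjusted over the list alone, ACB1 −1.57 ± 0.73, ELO1 −1.79 ± 1.47; adjusted p = 6.03e-06 with an estimated correlation). Ribosome biogenesis had 7 of 112 lower (18 adjusted over the list alone, NOP58 −2.3 ± 1.09; adjusted p = 0.0134 with an estimated correlation). General stress genes had 8 of 35 higher (16 adjusted over the list alone, GTT1 2.47 ± 0.52; adjusted p = 0.0043 with an estimated correlation). Osmotic response genes had 4 of 17 higher (7 adjusted over the list alone, GPP1 1.59 ± 0.4; adjusted p = 0.00195 with an estimated correlation) and iron-responsive genes 3 of 20 (5 adjusted over the list alone, FIT2 3.36 ± 1.5, FIT3 1.93 ± 0.4; adjusted p = 0.0117 with an estimated correlation). Respiratory chain genes had 4 of 33 higher (5 adjusted over the list alone, median 0.65, QCR6 2 ± 1.41; adjusted p = 0.0474 with an estimated correlation). Glycolysis had 2 of 16 higher (11 adjusted over the list alone, PGI1 1.68 ± 0.8; adjusted p = 0.0446 with an estimated correlation). Pheromone response genes had 2 of 16 higher (3 adjusted over the list alone, KAR4 1.79 ± 1.16; adjusted p = 0.00234 with an estimated correlation). Genes specific to mating type a had 1 of 7 higher (2 adjusted over the list alone, AGA2 2.14 ± 1.44; adjusted p = 0.0474 with an estimated correlation). Zap1 targets had 3 of 17 lower (5 lower and 1 higher adjusted over the list alone, IZH2 −3.18 ± 0.8; adjusted p = 0.0446 with an estimated correlation). Of single genes, NCE103 was at 6.66 ± 4.4, the cell wall protein gene CWP1 at 4.69 ± 1.25 (adjusted p = 2.4e-07), TMA10 at 4.77 ± 5.96 and RGI1 at 4.39 ± 4.17, the last 2 with flask 4 apart at 15.21 and 11.74. IZH4 was at −6.4 ± 3.24, OLE1 at −6.38 ± 6.25 with flask 2 apart at −17.26, TIP1 at −4.81 ± 2.57 and FAA4 at −4.5 ± 2.87. The count of 166 was 91, 85 and 110 without flask 0, 1 or 4. It was 32 on the Ontario chips alone, where the named genes other than CWP1 lost their call. TMA10 lost it without flask 0, 1 or 4 (5.08, 5.21 and 2.15), and OLE1 without flask 0, 1, 3 or 4 (−7.37, −6.45, −7.1 and −7.31).

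Recovery was also set against t60 within wild type. CWP1 was 6.86 ± 1.61 higher at t120 than at t60 (SD, n = 4 flasks, adjusted p = 4.7e-09), FIT2, a siderophore-binding wall protein, 5.96 ± 2.46, GLN1 4.79 ± 1.19 and ADE17, of purine synthesis, 4.68 ± 0.77. IZH4 differed by −12.54 ± 3.73, OLE1 by −11.69 ± 8.54, IZH1 by −9.22 ± 2.31 and IZH2 by −8.15 ± 0.97 (adjusted p = 1.2e-07, 0.001, 8e-07 and 4.7e-09). Ribosome biogenesis had 88 of 112 members lower at t120 than at t60 (99 adjusted over the list alone, median −2.19, adjusted p = 0.000158 with an estimated correlation), and glycolysis 12 of 16 higher (14 adjusted over the list alone, median 2.22, adjusted p = 0.0377 with an estimated correlation). These are 2 of the 8 lists that held with an estimated correlation in this comparison. Between t60 and t90, 1505 genes differed (712 higher, 793 lower at t90), and 1187 between t60 and t120 (548 higher, 639 lower). The counts were 911 without flask 2 for t90, 769 and 599 without flask 1 or 2 for t120, and 945 and 593 on the Ontario chips alone. Of 123 genes past the threshold at both t60 and t90, 102 had opposite directions, 56 higher and then lower and 46 lower and then higher. Independent lists of these sizes would share 54.3 genes, and the t0 sample shared by both ratios pushes toward the same direction.

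The same question was asked of each deletion strain at t60 and t120. At t60 the counts were 721 in dCIN5, 30 in dGLN3, 1150 in dHAP4, 11 in dHMO1, 1246 in dSWI4 and 993 in dZAP1. In dCIN5, NCE103 rose to 7.77 ± 0.24 (n = 4) and EFM6 to 5.89 ± 1.02, and YKL111C (−4.13 ± 1.41) and GDS1 (−3.23 ± 0.33) fell. In NCE103, EFM6 and YKL111C 1 flask stood apart (flasks 4, 1 and 2). In dGLN3, YDR042C rose to 3.54 ± 1.56 and ATG29, which overlaps SET6 and had values in 2 flasks, to 4.86 ± 2.22, while BDH1 (−2.46 ± 1.45) and LYS12 (−2.23 ± 1.61) fell. In dHAP4 the phosphate transporter gene PHO84 (6.81 ± 0.62) and EFM6 (6.66 ± 0.64) rose, and ZEO1 (−5.51 ± 1.26) and GPM2 (−3.67 ± 1.04) fell. In dHMO1, KNH1 (2.92 ± 0.39, n = 3) and the phospholipid methyltransferase gene OPI3 (2.76 ± 0.77) were higher and PHO85 (−2.65 ± 0.49) and REE1 (−2.17 ± 0.37) lower. In dSWI4, EFM6 (6.71 ± 0.89) and NCE103 (6.35 ± 2.69) rose, and BAR1, a protease that degrades alpha factor (−4.56 ± 0.31, n = 3), and NCE102 (−4.57 ± 1.38) fell. In dZAP1, OLE1 (6.45 ± 1.74) and IZH1 (5.45 ± 1.26) rose, and IDH1 (−4.03 ± 0.32) and IDH2 (−3.93 ± 0.48) fell. All these genes passed an adjusted p of 0.05 in limma, the highest being 0.043 for PHO85. Those of dGLN3 were all lost without flask 1. BDH1 and LYS12 were also lost without flask 3, 4 or 5, YDR042C without flask 3 or 4 and ATG29 without flask 5. The calls of dHMO1 were lost without flask 1, 2 or 4 and with the sign of flask 2 or 4 turned (OPI3 1.77 and 1.18). OLE1 of dZAP1 was lost without flask 3, 4 or 5 (7.19, 6.63 and 6.02).

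Of the genes past the threshold in these strains at t60, 394 in dCIN5, 19 in dGLN3, 548 in dHAP4, 9 in dHMO1, 546 in dSWI4 and 503 in dZAP1 had also changed the same way in wild type, against 58.6, 2.6, 93.2, 0.8, 99.3 and 80.3 for independent lists. No array is shared between these tests. Ribosome biogenesis had 56 of its members higher at t60 in dCIN5, 88 in dHAP4, 69 in dSWI4 and 74 in dZAP1 (adjusted p = 0.00166, 0.119, 4.38e-05 and 2.16e-06 with an estimated correlation). It had 2 higher in dGLN3 and 0 in dHMO1 (0.482 and 0.575 with an estimated correlation). At t120 the counts were 55 in dCIN5, 38 in dGLN3, 177 in dHAP4, 422 in dSWI4 and 251 in dZAP1, and 0 in dHMO1, where limma gave 342 genes at an unadjusted p below 0.05. With the sign of flask 2 or 4 turned, dHMO1 had 0 genes at t60 and at t120. Without the arrays that resembled the other phase the counts were 610 and 98 in dGLN3, 316 at t120 in dHAP4, and 348 and 1 in dHMO1. Single flasks mattered too. At t60 the count was 381, 386 and 136 without dCIN5 flask 1, 3 or 4, and 0, 592, 1, 0 and 4 without dGLN3 flask 1, 2, 3, 4 or 5. It was 485 and 547 without dHAP4 flask 2 or 3, 0 without dHMO1 flask 1, 2 or 4 and 155 without flask 3, 812 and 674 without dSWI4 flask 1 or 2, and 559, 523 and 563 without dZAP1 flask 3, 4 or 5. At t120 it was 116 and 5 without dCIN5 flask 2 or 4, 144, 24, 0 and 0 without dGLN3 flask 1, 3, 4 or 5, and 27 without dHAP4 flask 2. It was 160, 262 and 267 without dSWI4 flask 2, 3 or 4, and 94, 80 and 119 without dZAP1 flask 3, 4 or 5.

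**Figure D4:**
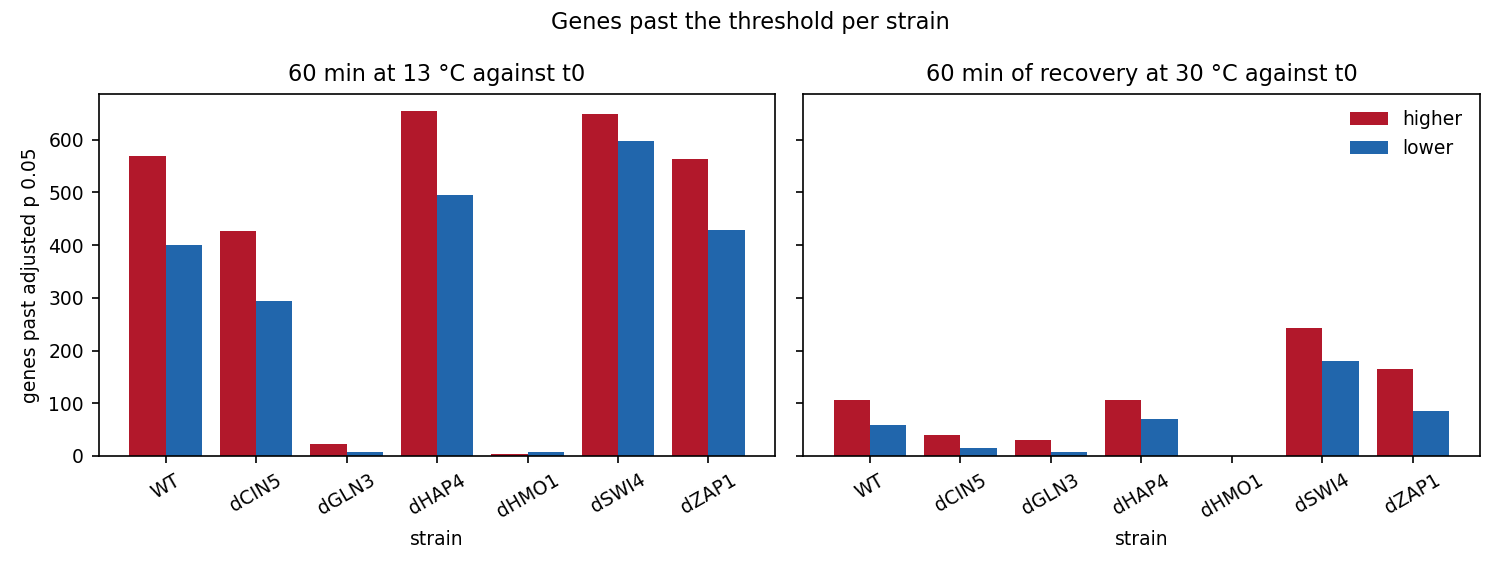
Number of genes past adjusted p = 0.05 (y axis) in each strain at t60 and t120 (x axis), higher and lower than t0 shown separately. Counts at t60 ran from 11 in dHMO1 to 1246 in dSWI4, and at t120 from 0 in dHMO1 to 422 in dSWI4.

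Whether the response differs without a factor was asked by testing deletion minus wild type, on the mean of t30 and t60 (cold) and of t90 and t120 (recovery). The flask values behind the printed means and SDs average the times that a flask had, which in some flasks was only 1. The printed means therefore need not differ by exactly the fitted difference. All deletion flasks held the antibiotic G418, which wild-type flasks did not, so that strain and medium cannot be told apart in any of these 12 comparisons. Wild-type flask 0 was also of another background (BY4739) than the deletion strains and the other wild-type flasks (BY4741). In dCIN5 the deleted gene was measured on 17 of 20 arrays with a mean size of 0.48 (highest 2.11), against 1.06 in wild type. Both channels of a deletion array lack the gene, so its ratio checks the label only weakly, here and in the other strains. In cold 0 genes differed by limma (442 at an unadjusted p below 0.05). In recovery 4 did, all higher in dCIN5: JLP2 by 3.15 ± 0.48 (SE; 2.47 ± 1.54, SD, n = 4, against −0.68 ± 0.64, n = 5, adjusted p = 0.00037) and the aconitase gene ACO1 by 2.87 (2.02 ± 0.31 against −0.85 ± 0.97). The others were ADE6, of purine synthesis, by 2.65 (3.25 ± 0.9 against 0.6 ± 0.54, with wild-type flask 2 apart at 1.52) and the kinase gene HRK1 by 2.12 (1.43 ± 0.48 against −0.57 ± 0.81). Tricarboxylic acid cycle genes were higher as a group, 1 of 11 past the threshold (4 adjusted over the list alone, median 0.85, adjusted p = 0.0204 with an estimated correlation). Osmotic response genes, tied to Cin5, were not called in cold (0 of 17 past the threshold; adjusted p = 0.695) or recovery (0.92; median −0.12, mean 0.03). The recovery count was 2 and 11 without wild-type flask 0 or 2, and 9, 26 and 1 without dCIN5 flask 1, 2 or 4. It was 1 on the Ontario chips alone and 8 with a dye term. The cold count was 9 and 4 without dCIN5 flask 2 or 3. The call of JLP2 held without any 1 flask, while ACO1 lost it without wild-type flask 0 or dCIN5 flask 4, ADE6 without dCIN5 flask 3 or 4, HRK1 without wild-type flask 0 or 1 or dCIN5 flask 4, and all 3 on the Ontario chips alone (2.94, 2.48 and 1.75).

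Without Gln3, genes of amino acid synthesis were lower in cold than in wild type. GLN3 itself had a mean size of 0.64 on 20 arrays of dGLN3 and 0.79 in wild type. ARO5 differed by −5.35 ± 0.67 (SE; −1.11 ± 1.18, SD, n = 5, against 4.48 ± 2.01, n = 5, adjusted p = 4.9e-06), ARG4 by −5.5 ± 1 (−1.39 ± 1.5 against 4.48 ± 1.94) and the methyltransferase gene TMT1 by −4.04 (−1.13 ± 1.42 against 2.93 ± 1.19). RPL7B was 2.39 ± 0.55 and MET2 2.07 ± 0.43 higher. The amino acid synthesis list had 7 of 48 members lower and 41 not past the threshold (17 lower and 1 higher adjusted over the list alone, median −0.63, adjusted p = 1.53e-10, and 0.0168 with an estimated correlation). Among them were the ornithine transporter gene ORT1 (−2.97 ± 0.47, SE), LYS1 (−3.72 ± 0.69) and LEU4 (−1.95 ± 0.38). In recovery, among genes whose flask means did not overlap between the strains, the difference was 5.03 ± 0.98 in ADE6 (6.04 ± 2.21 against 0.6 ± 0.54), −3.77 in the ribonucleotide reductase gene RNR4 (−4 ± 1.95 against 0.08 ± 0.8), −3.33 in TDH1, −3.03 in OPI3 and −3.02 ± 0.45 in PHO11 (−0.21 ± 0.53 against 2.78 ± 0.67; adjusted p = 0.00025). The iron-sulfur scaffold ISU1 (by 2.49), the catalase gene CTT1 (by 2.46) and JLP2 (by 2.15) were higher. Glycolysis had 5 of 16 lower (8 adjusted over the list alone, median −1.56, adjusted p = 0.00456 with an estimated correlation), such as PGI1 and CDC19 (both −2.31 ± 0.51). Phosphate-responsive genes had 4 of 15 lower (9 adjusted over the list alone, median −1.52, adjusted p = 0.000504 with an estimated correlation), such as PHO5 (−2.38 ± 0.39). Gln3 targets were not called in cold (0 of 27 past the threshold; adjusted p = 0.951) or recovery (0.807; 3 higher and 5 lower adjusted over the list alone). In all, 21 genes differed in cold (3 higher, 18 lower) and 51 in recovery (19 and 32). In cold the count was 11, 32, 11 and 12 without wild-type flask 1, 2, 3 or 4 and 10 without dGLN3 flask 4, and 32 with a dye term. In recovery it was 28, 30, 19 and 22 without wild-type flask 0, 2, 3 or 4, 7 without dGLN3 flask 5, and 21 on the Ontario chips alone. ARO5, ARG4, TMT1 and PHO11 held without any 1 flask. ADE6 lost its call on the Ontario chips alone (4.86), MET2 without wild-type flask 4 or dGLN3 flask 1 or 4, CTT1 without wild-type flask 0 or 3 or dGLN3 flask 5, JLP2 without wild-type flask 3 or dGLN3 flask 5, and TDH1 without wild-type flask 2 or 3 or dGLN3 flask 5. RPL7B, ISU1, RNR4 and OPI3 lost theirs without most single flasks.

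In dHAP4, whose slides alone were all uncoated so that coating and strain cannot be told apart, HAP4 had a mean size of 0.59 (1.01 in wild type). In cold 12 genes differed, 6 each way. PHO84 was 4.19 ± 0.93 higher (SE; 5.64 ± 0.55, SD, n = 4, against 1.57 ± 0.63, n = 5, adjusted p = 0.037), ECL1 by 2.61, HXT10, of the hexose transporter family, by 2.43 and the ferric reductase gene FRE3 by 2.04. GAS2 (−2.28), the nucleotidase gene SDT1 (−2) and PAU1 (−1.82) were lower. The PAU list had 2 of 23 members lower (15 adjusted over the list alone, median −1.47, adjusted p = 9.29e-20, and 0.0133 with an estimated correlation). Sulfur assimilation had 1 of 23 higher, MET2 at 2.01 ± 0.41 (5 adjusted over the list alone, median 0.44, adjusted p = 0.0245 with an estimated correlation). In recovery 2 genes differed: YFL012W-A by 6.56 ± 0.62 (7.25 ± 1.93, n = 3, against 0.74 ± 0.78; adjusted p = 2.5e-09) and GAT1, an activator of nitrogen genes, by 2.89 ± 0.44 (3.97 ± 0.64 against 1.09 ± 0.6). Overlap of YFL012W-A with other genes was not examined. Phosphate-responsive (median −0.84) and iron-responsive genes (−0.81) were lower and fatty acid synthesis (0.65) higher as groups, with 0 members past the threshold and 3, 4 and 0 adjusted over the list alone (adjusted p = 0.0209, 0.00261 and 0.00261 with an estimated correlation). Respiratory chain genes, the targets of Hap4, were not called in cold (0 of 32 past the threshold; adjusted p = 0.728) or recovery (0.579). In cold the count was 0, 34 and 4 without wild-type flask 1, 2 or 4, and 1, 0 and 1 without dHAP4 flask 1, 3 or 4. In recovery it was 4 without wild-type flask 2 or 4, 29 and 9 without dHAP4 flask 3 or 4, and 4 without the t90 array that resembled the cold phase. The genes named in cold all lost their call without dHAP4 flask 3 and each also without at least 1 wild-type flask. In recovery YFL012W-A held throughout and GAT1 was lost on the Ontario chips alone (2.59).

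In dHMO1, HMO1 had a mean size of 0.61 (1.12 in wild type). In cold 3 genes were lower than in wild type, among them FHN1 by −3.37 (0.92 ± 0.53, SD, n = 4, against 4.5 ± 1.52, n = 5, adjusted p = 0.023) and ATG45 by −2.11. In recovery 6 were lower, among them PHO11 by −3.02 ± 0.46 (−0.24 ± 0.3 against 2.78 ± 0.67; adjusted p = 0.00046), COS5 by −2.84, the mitochondrial aldehyde dehydrogenase gene ALD4 by −2.74 and PHO12 by −2.58. Phosphate-responsive genes had 2 of 15 lower in recovery (6 adjusted over the list alone, median −1.1, adjusted p = 0.000409 with an estimated correlation). Cytosolic ribosomal proteins, whose genes Hmo1 binds, were higher as a group in cold with 0 of 134 members past the threshold (median 0.79, adjusted p = 2.25e-22, and 0.412 with an estimated correlation) and not called in recovery (adjusted p = 0.815). With the sign of flask 2 turned, 151 genes differed in cold and 267 in recovery. With that of flask 4 turned, 10 and 2 differed. The list of phosphate-responsive genes stayed lower in recovery in both cases (adjusted p = 5.7e-06 and 4.4e-09), and cytosolic ribosomal proteins stayed higher in cold (1.1e-22 and 4.9e-11) but were lower in recovery with flask 4 turned (0.015). In recovery that list was also called higher without wild-type flask 2 (0.00093) and on the Ontario chips alone (0.0041), and lower without wild-type flask 3 (0.0049) or 4 (0.032). In cold the count of 3 was 1 and 0 without wild-type flask 1 or 2 and 0 without dHMO1 flask 1 or 3. In recovery it was 3, 1 and 1 without wild-type flask 0, 1 or 2 and 13, 104 and 1 without dHMO1 flask 1, 2 or 3, as well as 2 on the Ontario chips, 14 with a dye term and 1 without the arrays that resembled the other phase. PHO11 held in each case (−2.96 and −2.75 with flask 2 or 4 turned), and the other 5 named genes lost their call without wild-type flask 2 or dHMO1 flask 3. With a sign turned FHN1 still passed (−3.51 and −4.15), while COS5, ALD4 and PHO12 did not with flask 4 turned (−1.83, −2.54 and −2.06).

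In dSWI4 the strains differed more in recovery than in cold by count, 73 genes (46 higher, 27 lower) against 9 (3 and 6). SWI4 had a mean size of 0.22 (0.63 in wild type). In cold PHO84 was 3.96 ± 0.78 higher (SE; 5.41 ± 1.6, SD, n = 4, against 1.57 ± 0.63, n = 5, adjusted p = 0.025), the tRNA methyltransferase gene TRM5 by 3.22 and the S-adenosylmethionine synthetase gene SAM2 by 2.34. GIC2, an effector of Cdc42 (−2.43), DUF1 (−2.18), PAU13 (−2.12) and HEL1 (−1.86) were lower. In recovery YFL012W-A was 6.66 ± 0.62 higher (7.41 ± 1.88 against 0.74 ± 0.78), ADE6 4.17 ± 0.67, NFG1 by 3.72 and the mannosyltransferase gene KTR2 by 3.7. PHO12 (−3.64 ± 0.48; −1.05 ± 1.05 against 2.59 ± 0.16), PHO11 (−3.05 ± 0.46), the siderophore transporter gene ENB1 (−2.78) and PHO3 (−2.64) were lower. General stress genes had 6 of 35 higher (14 adjusted over the list alone, median 1.07, adjusted p = 0.0158 with an estimated correlation), such as HSP12 (6.91 ± 1.08) and ALD3 (2.9 ± 0.46). The tricarboxylic acid cycle had 3 of 11 higher (6 adjusted over the list alone, ACO1 2.24 ± 0.55; adjusted p = 0.0277 with an estimated correlation). The respiratory chain had 1 of 33 higher (5 adjusted over the list alone, RIP1 1.79 ± 0.44; adjusted p = 0.0158 with an estimated correlation). Mitochondrial ribosomal proteins (median 0.62) and fatty acid synthesis (0.33) were higher as groups with 0 members past the threshold (adjusted p = 0.0158 and 0.0433 with an estimated correlation), the latter lost without wild-type flask 1, 2 or 4 or dSWI4 flask 1 or 4. Phosphate-responsive genes had 4 of 14 lower (5 adjusted over the list alone, PHO86 −1.94 ± 0.4; adjusted p = 9.79e-05 with an estimated correlation). Iron-responsive genes had 5 of 20 lower (8 adjusted over the list alone, FET3 −2.74 ± 0.59, ARN2 −2.26 ± 0.45; adjusted p = 0.000924 with an estimated correlation). G1 cell cycle genes, the targets of Swi4, were not called in cold (0 of 26; adjusted p = 0.714; median −0.02, mean 0.07; 3 higher and 1 lower adjusted over the list alone) or recovery (0.425), where TOS6 was lower (−2.59 ± 0.53; adjusted p = 0.0048). With a term for slide coating the counts were 2 and 8. In cold the count was 4, 0, 19 and 1 without wild-type flask 0, 1, 2 or 3, and 5, 2, 4 and 1 without dSWI4 flask 1, 2, 3 or 4. In recovery it was 42 without dSWI4 flask 2, and 38 on the Ontario chips. All 7 named genes of the cold lost their call without wild-type flask 1 and each also without dSWI4 flask 2 or 4. Those of recovery held without any 1 flask, and KTR2 and ENB1 were lost on the Ontario chips alone (3.02 and −2.52).

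In dZAP1 the deleted gene, measured on 17 of 20 arrays, had a larger mean size (1.22, highest 5.06) than in wild type (0.93), although both channels should lack it. In cold 5 genes were lower, among them ICY1 by −2.82 (−0.01 ± 0.82, SD, n = 4, against 2.97 ± 1.38, n = 5, adjusted p = 0.014). In recovery 18 differed (11 higher, 7 lower). CTT1 was 5.97 ± 0.59 higher (SE; 5.89 ± 1.99 against −0.08 ± 0.61; adjusted p = 5.5e-09), ADE6 5.83 ± 0.72 (6.43 ± 2.13 against 0.6 ± 0.54), YFL012W-A by 5.76 and the aldehyde dehydrogenase gene ALD3 by 3.19. CAR1 (−2.44), PHO11 (−2.31), YCLX11W (−2.27) and the iron permease gene FTR1 (−1.93) were lower. General stress genes had 5 of 35 higher (14 higher and 1 lower adjusted over the list alone, median 1.18, adjusted p = 0.00894 with an estimated correlation), such as MSC1 (3.3 ± 0.58) and RTN2 (2.66 ± 0.51). Sulfur assimilation (median −0.86), phosphate-responsive (−1.11) and iron-responsive genes (−1.14) were lower as groups, with 0, 1 and 1 members past the threshold and 5, 5 and 7 lower adjusted over the list alone (adjusted p = 0.0241, 0.00205 and 0.0185 with an estimated correlation). Fatty acid synthesis was higher (median 0.53; 0 past the threshold, 2 adjusted over the list alone, adjusted p = 0.00894 with an estimated correlation), a call lost without dZAP1 flask 2 or 5 (0.065 and 0.055). Zap1 targets were not called in cold (0 of 17; adjusted p = 0.0994; 2 lower adjusted over the list alone), where ZRT1 was at −2.94 ± 0.7 (SE; adjusted p = 0.058) and ZPS1 at −2 ± 0.55 (0.17), nor in recovery (0.601; median −0.03, mean 0.15). Without wild-type flask 3 they were called in cold (0.032). In cold the count was 0, 25 and 3 without wild-type flask 1, 2 or 4 and 1 without dZAP1 flask 5, and 14 with a dye term. In recovery it was 43 without wild-type flask 2, 46 and 9 without dZAP1 flask 2 or 5, and 29 with a dye term. CTT1, ADE6, YFL012W-A and ALD3 held throughout, whereas ICY1 lost its call without wild-type flask 1 or 4 or dZAP1 flask 2 or 5, and CAR1, PHO11, YCLX11W and FTR1 without dZAP1 flask 5.

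Phosphate-responsive genes were lower than in wild type in recovery in all 6 deletion strains, with list medians from −1.52 to −0.7. On the Ontario chips alone the median was −0.25 in dCIN5 and −0.55 in dHAP4, and −0.36 in dCIN5 without wild-type flask 0. The list passed with an estimated correlation in dGLN3, dHAP4, dHMO1, dSWI4 and dZAP1 and not in dCIN5 (adjusted p = 0.225). Over t90 and t120 the mean of the flask medians was 1.32 ± 0.58 in wild type (SD, n = 5), 0.62 ± 0.34 in dCIN5, 0.03 ± 0.18 in dGLN3, 0.59 ± 0.6 in dHAP4, 0.13 ± 0.31 in dHMO1, −0.04 ± 0.11 in dSWI4 and 0.31 ± 0.31 in dZAP1. In cold the PAU list was lower in all 6 strains (medians −1.47 to −0.96), and held with an estimated correlation in dHAP4 alone (0.0133, against 0.13 to 0.412 in the others). These comparisons share the wild-type flasks. With unchanged strains set against them in 1000 simulations, all 6 medians had the same direction in 39.4% for the phosphate list and 47.2% for the PAU list, and in 0 did all 6 lie as far from 0 as the observed ones. A single median as large as the largest observed came in 0 simulations for the phosphate list and in 23 for the PAU list. The simulations only turned the signs of residuals of whole flasks. With 5 wild-type flasks few sign patterns exist, so that 0 of 1000 claims a finer resolution than they have. All 6 medians also had the same direction for the PAU list and glycolysis in recovery and iron-responsive genes in cold. There 84, 54 and 18 simulations lay as far from 0. Part of the excess may still come from the shared flasks.

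**Figure D5:**
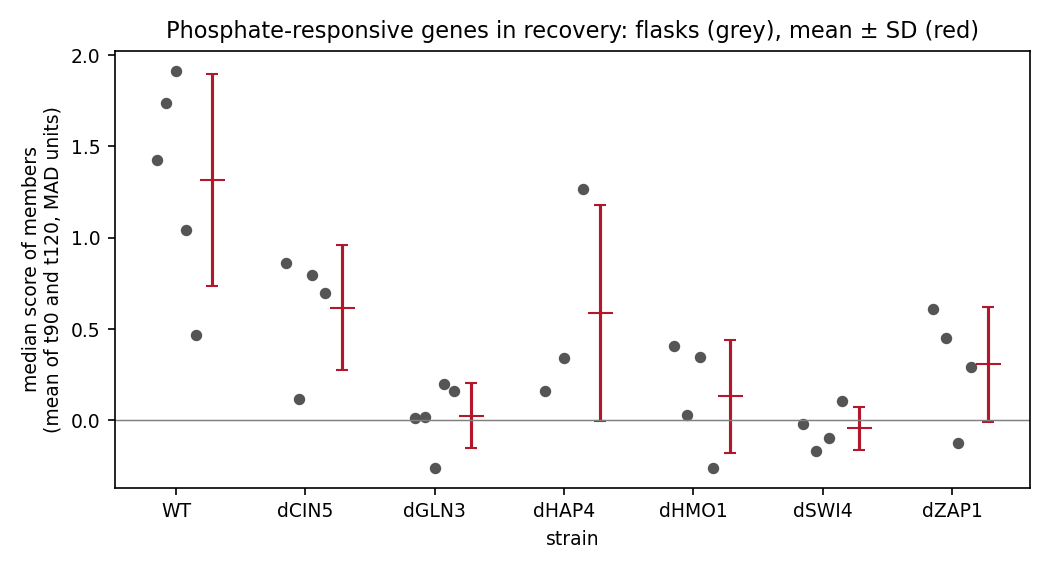
Median score of the phosphate-responsive genes over t90 and t120 (y axis, units of the array's spread) in each flask (grey points) by strain (x axis), with the mean and SD of each strain in red. Wild-type flasks ran from 0.47 to 1.92 and those of dSWI4 from −0.16 to 0.1.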

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

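The tests on the 4 arrays, on turned dHMO1 ratios and on the dHMO1 t0 sample were chosen after seeing the result; those on dye, chip source, single wild-type flasks and other splits of the flasks were chosen before.

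Arrays far from the others of their group, by a test of gaps that chance meets in about 1 group in 20 and that was met in 2 of 32 groups, were dGLN3 t60 flask 2 (rank correlation with its phase −0.32; others 0.59 to 0.69) and dZAP1 t60 flask 2 (0.53; others 0.73 to 0.75). The same test singled out 10 of 176 sets of gene values: YGR035C in wild-type flask 1 at t15 (3.65), HXT2 in flask 2 at t15 (13.42), IDH2 in flask 0 at t60 (−1.06), TMA10 and RGI1 in flask 4 at t120 (15.21 and 11.74), OLE1 in flask 2 at t120 (−17.26), ADE6 in flask 2 in recovery (1.52), and, in dCIN5 at t60, NCE103 in flask 4 (7.41), EFM6 in flask 1 (4.37) and YKL111C in flask 2 (−2.04).

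Differences between a deletion strain and wild type were listed because the strains differ by a test: 4 genes in recovery for dCIN5, 21 in cold and 51 in recovery for dGLN3, 12 and 2 for dHAP4, 3 and 6 for dHMO1, 9 and 73 for dSWI4, and 5 and 18 for dZAP1. Cytosolic ribosomal proteins in dHMO1 minus wild type in cold had an adjusted p of 2.25e-22 (0.412 with an estimated correlation).

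Each deletion comparison was repeated on 100 splits of the same flasks, or 56 for dHAP4 in recovery, the real one included. Taking each comparison alone, the share of splits with as many genes as the real one was under 0.05 in the following. They were dGLN3 in cold (21 genes, highest other 18, 1 of 100 splits as large) and recovery (51, highest other 162, 3 of 100) and dHAP4 in cold (12, highest other 31, 2 of 100). Also under it were dHMO1 in cold (3, highest other 16, 4 of 100), dSWI4 in cold (9, highest other 14, 2 of 100) and recovery (73, highest other 78, 3 of 100) and dZAP1 in cold (5, highest other 26, 2 of 100). Without an adjustment over the 12, and with no share below 1 of 100 within reach, this does not exclude chance. The share was 0.05 or more for dCIN5 in cold (0, highest other 26, 100 of 100) and recovery (4, highest other 453, 26 of 100) and dHAP4 in recovery (2, highest other 171, 23 of 56). The same held for dHMO1 in recovery (6, highest other 193, 13 of 100) and dZAP1 in recovery (18, highest other 202, 11 of 100). Except for dGLN3 in cold, at least 1 other split called more genes than the real one. Splits that call several times the real count point to a structure among the flasks, not tested further. In cold the highest other split of dHAP4 and dZAP1 only moved wild-type flask 2 to the deletion side, and that of dCIN5 and dGLN3 exchanged it for flask 2 of the deletion strain, so that these largely repeat the strain comparison. Without wild-type flask 2 the counts were 34 in dHAP4, 25 in dZAP1, 0 in dCIN5 and 32 in dGLN3. The highest other split followed the dyes for dCIN5 and dZAP1 in recovery, and nearly so for dGLN3 in recovery, dHMO1 in cold and dSWI4 in recovery; with a dye term the counts were 8, 29, 56, 3 and 98. Within a strain, the signs of the flasks' arrays at the tested time were turned. For recovery minus t60, the t60 and the recovery array of a flask were exchanged instead. Either way gives too few splits (4 to 16) to say more than the real and highest other counts. For wild type these were 668 and 22 at t15, 933 and 45 at t30, 971 and 4 at t60, 346 and 66 at t90, 166 and 37 at t120, 1505 and 20 for t90 minus t60 and 1187 and 10 for t120 minus t60. At t60 and t120 they were 721 and 0, and 55 and 1, in dCIN5; 30 and 493, and 38 and 75 in dGLN3, where 2 of 8 splits were as large; 1150 and 3, and 177 and 2, in dHAP4; 11 and 1, and 0 and 0 (8 of 8 splits), in dHMO1; 1246 and 2, and 422 and 0, in dSWI4; and 993 and 0, and 251 and 1, in dZAP1.

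The 4 arrays that resembled the other phase may carry another time label than the sample had, or a ratio turned the wrong way. Within their own flask, 4 of 4 were closer to arrays of the other phase, the last by only 0.46 against 0.45; the arrays had been picked by such a likeness, so that this fits a wrong time label without testing it independently. Turning the ratio brought 1 of 4, dHMO1 t90 flask 3, up to its group mates, which argues against a turned ratio for the other 3. A flask that responded differently stays open.

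In dHMO1, arrays of flask 2 (shifted sample in Cy5) correlated negatively with those of flask 4 (Cy3), from r = −0.69 to −0.02 across genes. Their difference correlated with the mean dye difference of the other strains at r = −0.25 across genes, but from −0.45 to 0.28 with single strains, whose dye differences had little in common (pairs from −0.62 to 0.39, median 0.14), so that a dye effect stays open. A turned ratio is argued against by the cold arrays of both flasks, which correlated positively with the cold profile (0.33 for the lower flask). A t0 sample that differed between flasks could leave a mark shared by all arrays of a flask. The lowest median correlation within a dHMO1 flask was 0.13, in flask 1, and flasks of dCIN5, with no such conflict, were also above 0 (0.05 to 0.33). Between cold and recovery arrays of the same flask the median was 0.42 and 0.63 in dHMO1 flasks 2 and 4. It was 0.03 and 0.22 in flasks 1 and 3, and at most 0.36 in a flask of any other strain. Flasks 2 and 4 thus carry such a shared mark, but its source is not shown. A t0 difference stays open, as do biological differences between the cultures, which were not tested.

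Phosphate-responsive genes were lower in recovery than in wild type in all 6 deletion strains (mean of the medians −1.05). Chip source or any 1 wild-type flask may account for part of the size but not for the direction: the mean was −0.76 without the GCAT chips and, of the wild-type flasks left out, nearest to 0 without flask 0 (−0.84). In dCIN5 little was left, −0.25 and −0.36. Whether G418 lowers these genes cannot be told, since 0 deletion flasks grew without it. That each deletion acts on these genes stays open.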

How the results depend on the processing

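Of 198 results on gene lists 52 and of 140 named genes 76 were the same under every alternative run on them. The stricter threshold, the fit of all strains, flask number as a block, the coating term and t60 or t120 alone were run on the gene counts only. For lists, 138 of the calls were weaker with an estimated correlation, 47 on the Ontario chips only, 47 with genes measured on every array and 10 with a dye term. Centring the arrays, with or without scaling, changed 1 list call, that of cytosolic ribosomal proteins in wild type at t120 (adjusted p = 0.053). These steps could change little, since the deposited values already had nearly the same median and spread on every array. Robust moderation, which leaves the estimates as they are, ended 3 list calls and 5 named-gene calls: BTN2 in wild type at t15 (adjusted p = 0.094), HSP42 at t60 (0.052), TMA10 and OLE1 at t120 (0.059 and 0.12) and PHO84 in dHAP4 minus wild type in cold (0.058). The cause of the changes below was not tested. A stricter threshold, fewer genes or fewer flasks can leave less to find. Leaving out a flask also raised some counts, as in dGLN3 at t60, from 30 to 592 without flask 2.

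At an adjusted p below 0.01 the counts were, in wild type, 293 (t15), 453 (t30), 479 (t60), 134 (t90), 70 (t120), 879 (t90 minus t60) and 554 (t120 minus t60). At t60 and t120 they were 251 and 21 in dCIN5, 3 and 0 in dGLN3, 377 and 25 in dHAP4, 641 and 164 in dSWI4, 509 and 90 in dZAP1, and 2 at t60 in dHMO1. Against wild type in cold and recovery they were 10 and 10 in dGLN3, 0 and 36 in dSWI4, 0 and 10 in dZAP1, 0 in cold in dHAP4, and 0 and 1 in dHMO1. On the Ontario chips only the counts were 464 (t60), 195 (t90), 32 (t120), 945 and 593 (t90 and t120 minus t60) in wild type. Against it they were 1 (dCIN5), 21 (dGLN3) and 2 (dHMO1) in recovery and 16 and 38 in dSWI4. With a dye term they were 47 in dGLN3 at t60 and 325 in dHAP4 at t120. Against wild type they were 8 (dCIN5 recovery), 32 (dGLN3 cold), 14 (dHMO1 recovery), 14 and 29 (dZAP1). With genes measured on every array they were 17 in dGLN3 and 3 in dHMO1 at t60. Against wild type they were 12 and 16 in dGLN3, 7 and 1 in dHAP4, 1 in dHMO1 in cold, 48 in dSWI4 in recovery and 1 in dZAP1 in cold. Without a replicate block they were 730 for wild type t120 minus t60. Against wild type they were 17 in dCIN5 in recovery, 38 and 97 in dGLN3, 55 and 10 in dHAP4, 12 and 56 in dHMO1, 37 and 158 in dSWI4, and 24 and 75 in dZAP1.

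In 1 fit of all strains the counts were 88 in dCIN5 at t120, 271 and 211 in dGLN3, 280 in dHAP4 at t120, 193 and 14 in dHMO1, and 797 and 277 in dSWI4. Against wild type they were 2 in dCIN5 in cold, 3 and 4 in dHAP4, 5 and 28 in dHMO1 and 3 in dSWI4 in cold. Flask number as a block across strains gave 16 in dGLN3, 1 in dHMO1 and 6 in dCIN5 in recovery and 21 in dZAP1 in cold. Flasks of equal number were no more alike than others (mean r −0.04 to 0.05), so that this block rests on no pairing. A slide coating term gave 2 and 8 for dSWI4. With t60 alone the cold counts were 6 (dGLN3), 2 (dHAP4), 0 (dHMO1), 0 (dSWI4) and 2 (dZAP1), and with t120 alone the recovery counts 9 (dGLN3), 9 (dHAP4), 2 (dHMO1) and 32 (dSWI4). Of the alternatives chosen after seeing the data, leaving out the arrays that resembled the other phase gave 610 and 98 in dGLN3, 316 at t120 and 4 against wild type in recovery in dHAP4, and 348, 1 and, in recovery against wild type, 1 in dHMO1. Turning the signs of dHMO1 flask 2 gave 0 at t60 and 151 and 267 against wild type, and of flask 4 gave 0, 10 and 2.

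Leaving out 1 flask in turn, the counts ranged in wild type over 274 to 626 (t15), 482 to 770 (t30), 541 to 938 (t60), 139 to 293 (t90), 85 to 139 (t120), 911 to 1401 (t90 minus t60) and 599 to 1149 (t120 minus t60). At t60 and t120 they ranged over 136 to 793 and 5 to 116 in dCIN5, 0 to 592 and 0 to 144 in dGLN3, 485 to 870 and 27 to 168 in dHAP4, 0 to 155 in dHMO1 (t60), 674 to 967 and 160 to 346 in dSWI4, and 523 to 873 and 80 to 204 in dZAP1. Against wild type in cold and recovery they ranged over 0 to 9 and 1 to 26 in dCIN5, 10 to 32 and 7 to 52 in dGLN3, 0 to 34 and 2 to 29 in dHAP4, 0 to 4 and 1 to 104 in dHMO1, 0 to 19 and 42 to 106 in dSWI4, and 0 to 25 and 9 to 46 in dZAP1.

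Some list results turned direction, each with 0 members past the threshold. Cytosolic ribosomal proteins, called higher in wild type at t120 (adjusted p = 0.0498, and 0.696 with an estimated correlation), were lower on the Ontario chips only (0.28) and without wild-type flask 2 (0.05), with a range over all alternatives of 1e-08 to 0.86. Their recovery difference from wild type, called lower in dCIN5, dSWI4 and dZAP1 (0.0174, 0.00933 and 0.00776, and 0.808, 0.682 and 0.714 with an estimated correlation), was higher on the Ontario chips only (0.56, 0.91 and 0.94) and without wild-type flask 2 (0.51, 0.6 and 0.71). With 1 flask left out dCIN5 reached 0.65, and the ranges over all alternatives were 2.5e-09 to 0.81, 5.6e-09 to 0.91 and 1.4e-09 to 0.94. In dHMO1 in recovery they were called higher on the Ontario chips only (0.0041) and without wild-type flask 2 (0.00093). They were called lower without wild-type flask 3 (0.0049) or 4 (0.032) or with the sign of flask 4 turned (0.015); 1 flask left out gave 0.00093 to 0.86, and all alternatives 0.00093 to 0.98. In dHMO1 in cold the call was lost with an estimated correlation (0.41) and otherwise ran from 6.7e-28 to 4.9e-11. The proteasome in dCIN5 in recovery, called higher at 0.0173 (0.465 with an estimated correlation), turned without dCIN5 flask 4 (0.7; range 8.9e-05 to 0.7), and ribosome biogenesis in dHAP4 in recovery, called higher at 0.0145 (0.782 with an estimated correlation), without dHAP4 flask 4 (0.025) and without the arrays that resembled the other phase (0.0047; up to 0.21 with 1 flask left out, range 1.2e-07 to 0.78). Zap1 targets in dZAP1 in cold were called without wild-type flask 3 (0.032; 0.032 to 0.31 with 1 flask left out, 0.032 to 0.44 over all alternatives).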

Other observations

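Cytosolic ribosomal proteins fell at t60 in strains where the list held with an estimated correlation: 39 of 136 members were lower in dCIN5 (65 lower and 1 higher adjusted over the list alone; median −1.08, adjusted p = 0.0336 with an estimated correlation), 69 of 135 in dSWI4 (100 and 1 adjusted over the list alone; median −1.16, 0.0433) and 39 of 135 in dZAP1 (47 and 1 adjusted over the list alone; median −0.98, 0.0244). These lists were picked after their values were seen. Heat shock proteins and chaperones had 13 of 27 members lower in dSWI4 at t60 (15 adjusted over the list alone; median −1.45, 0.0433).

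At t120, general stress genes were higher in dZAP1, with 20 of 35 members past the threshold (31 higher and 1 lower adjusted over the list alone; median 2.15, adjusted p = 5.23e-07 with an estimated correlation), while the proteasome had 8 of 32 members lower (16 adjusted over the list alone; median −0.88, 4.4e-05). In dSWI4 the respiratory chain, which makes ATP in mitochondria, had 16 of 33 members higher (24 adjusted over the list alone; median 1.35, 3.33e-07) and mitochondrial ribosomal proteins 18 of 64 (33 adjusted over the list alone; median 0.95, 6.02e-07). The respiratory chain was also higher in wild type (4 of 33, median 0.65, 0.0474), in dCIN5 (1 of 33 members past the threshold, 18 adjusted over the list alone; median 1.2, 1.01e-06) and in dHAP4, which lacks an activator of these genes (2 of 32, 3 adjusted over the list alone; median 0.66, 0.0048).

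Arrays of a strain at one time agreed less in recovery than in cold in every strain, with median correlations across genes of 0.516 and 0.189 in wild type, 0.446 and 0.213 in dCIN5, 0.45 and 0.167 in dGLN3, 0.598 and 0.106 in dHAP4, 0.332 and −0.031 in dHMO1, 0.556 and 0.393 in dSWI4, and 0.458 and 0.23 in dZAP1 (cold and recovery).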
